A study of Mus musculus with 64 samples.

How the data were processed

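The series holds RNA sequencing of whole colon from Swiss Webster mice kept under specific pathogen free (SPF) or germ-free (GF) conditions. Per the labels, mice were 8 to 12 weeks old, lived on a cycle of 12 h light and 12 h dark, and were assigned at random to vancomycin or PBS. Injections were intraperitoneal, 2 each day over 3 days with a last one on day 4, each of 100 µl holding 2.5 mg vancomycin in PBS or PBS alone. GF mice were moved from isolators to ISOcages while they were treated. Per the labels' protocols, libraries were made from 1000 ng of total RNA after poly(A) selection with the NEBNext Ultra II kit and sequenced on a NextSeq 550 as single-end reads of 75 cycles. Poly(A) selection leaves transcripts without a poly(A) tail, such as those of most histone genes, in low and variable yield.

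The submitters' processing notes name Trim Galore 0.6.2, cutadapt 3.5, Salmon and the genome build GRCm39. The deposited values were read as estimated counts per gene, of the kind Salmon gives from transcripts, in 1 table for the SPF libraries and 1 for the GF libraries. The names of the deposited files call the values normalized, and how is not given in the sources used here. Each table holds 35534 genes and 32 libraries, and each column was matched to a library by its name, with 0 columns of other samples. How transcripts were summed to genes, which annotation was used and whether strand was used are not given in the sources used here. Genes that share sequence with close copies, such as immunoglobulin segments, the Saa1 and Saa2 pair, histone genes and interferon-induced GTPase families, and genes that overlap others therefore have uncertain values. Gene symbols came from the files, and 4 of the 49 genes without one were named from the GENCODE vM21 annotation of build GRCm38, which also gave the order of genes along chromosomes. No coordinate was used across builds. A symbol held by more than 1 gene occurred 30 times, and such genes were told apart by Ensembl identifier.

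Whether the deposited estimated counts had been scaled was checked on the values, since the unit decides the test. In each of the 32 SPF and 32 GF libraries the smallest common value lay near 1 estimated count, from 0.978 to 1.01 in SPF and from 0.970 to 1.01 in GF libraries, so no depth scaling was visible. Of the values under 20, only 4.24% to 12.9% in an SPF library and 3.47% to 15.1% in a GF library lay within 0.01 of a whole number, so an adjustment of single genes before deposit, such as one for transcript length, is not excluded. The edgeR and DESeq2 results rest on this reading of the unit. Totals were 10044032 to 13615804 estimated counts per SPF library and 10513966 to 15736087 per GF library. The 10 most abundant genes took 5.34% to 7.54% of an SPF library and 4.85% to 7.54% of a GF library. The design fixed for the tests had named limma on log2 values as the main test, with edgeR in its place if the tables held counts or estimated counts, and this second form was used. Estimated counts were rounded to whole numbers before testing.

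Genes with a rounded value of at least 10 in at least 4 libraries were tested, 16938 in the SPF table and 16951 in the GF table. Each table was fitted with edgeR 4.0.16 (TMM scaling, glmQLFit and glmQLFTest, R 4.3.3) with 1 mean for each of its 8 groups of treatment and time of day. The vancomycin effect was the mean over the 4 times of vancomycin minus PBS within a time. Further contrasts gave the effect at each time, the treatment by time interaction (an F test of 3 contrasts), and the time-of-day effect within each treatment (an F test of 3 contrasts). All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Because the tables are separate, no level was tested between them. The difference between the SPF and GF effects was tested in 1 fit of all 64 libraries and 16 group means over 16604 genes tested in both tables, and used only differences within a table. CPM are counts scaled by the library total and its TMM factor. Fold changes are given with standard errors (SE) and CPM with standard deviations (SD) over libraries. Each SE is the size of the log2 fold change divided by the square root of the test's F, which is unreliable where the fold change is near 0.

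For 43 gene lists, camera (limma 3.58.1) tested whether members moved more than other genes, with a preset inter-gene correlation of 0.01, adjusted over the lists with at least 4 tested members. The same lists were tested with an inter-gene correlation estimated from the data, and with fry, which tests whether the members move one way on balance (its mixed p tests movement in either direction). Member counts were adjusted over all genes and also over the list alone. The lists, the tests, most alternatives and the rule for the genes named were fixed before the data were examined. That rule takes, among called genes with a mean value of at least 50 in one treatment and no predicted or antigen receptor segment name, the 8 largest changes in each direction for the effect over all times with the same sign at all 4 times, 5 per direction for the difference between SPF and GF, 3 per direction at each time, the 6 smallest p of each interaction and time-of-day test, the 4 smallest p in each list, and 11 genes in all cases. Where no gene passed, the 4 with the smallest p were taken.

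The similarity of the SPF and GF effects was a correlation across genes, set against 100 relabellings of treatment within times in the GF table. Library scores were mean log2 CPM of a list's members, with a prior count of 2. They were compared between treatments by permutation within times (100000 draws), with adjustment over the 14 tests. A colon position score (distal minus proximal Hox genes) and a clock index (output arm minus activator arm of the clock) came from 4 lists added after the data were seen. At a single time, the clock index was compared by an exact test over the 70 relabellings of 8 libraries. Counts of calls were also recomputed over 100 random splits of the libraries, 35 for a single time and 60 for the difference. The share of called genes within 10 tested genes of another along a chromosome was set against 10000 random sets. No 2 libraries of a group matched within sampling noise, with a chi-square per gene of 16.2 to 122.8 over 96 pairs.

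Alternatives fixed in advance were limma with pseudocounts 0.5 and 5, no filter on low values, a mean value filter of 50, quantile normalization, scaling by medians of ratios, array weights, B cell, smooth muscle and Y-linked covariates, a replicate block, a fit on the 8 libraries of 1 time, separate fits for the 2 tables, and leaving out each library. Alternatives added after the data were seen were DESeq2 1.42.0, limma with pseudocount 1, robust edgeR, library totals as the only scaling, a colon position covariate, T and NK cell and macrophage covariates for 3 gene lists, array weights and the other scalings, filters, covariates and engines at single times and in F tests, GF libraries with Y-linked expression only, and the effect averaged over ZT5 and ZT23 alone in the fit of all libraries of a table. In simulated tables with 200 changed genes, the SPF effect step, run on 16785 genes, recovered 64.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold. The GF effect step (16786 genes) recovered 61.2%, 77.6% and 97.0%, and the step for the difference (16451 genes) 38.8%, 65.7% and 97.0%. The SPF interaction step recovered 5.97%, 28.4% and 74.2%, that at SPF ZT17 35.8%, 50.7% and 89.4%, and that for time of day after PBS in SPF mice 22.4%, 62.7% and 90.9%. In the GF table (16784 genes) these 3 steps recovered less: 2.99%, 14.9% and 54.5% for the interaction, 7.46%, 31.3% and 74.2% at ZT17, and 8.96%, 40.3% and 83.3% for time of day after PBS. False calls in these tables numbered 12 for the SPF effect, 5 for the GF effect and 8 for the difference, and for SPF and GF libraries 20 and 3 at ZT17, 3 and 2 for the interaction, and 5 and 4 for time of day after PBS. The 20 at SPF ZT17 stood beside 24, 34 and 59 recovered genes, a larger share than the 5% aimed at. Simulated genes were independent, so these numbers leave out the correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.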

Results

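Whole colon from Swiss Webster mice, an outbred laboratory stock, was profiled by poly(A)-selected RNA sequencing in 64 libraries. Mice were specific pathogen free (SPF), with a gut microbiota, or germ-free (GF), raised without microbes. Each kind received vancomycin, a glycopeptide antibiotic that blocks cell wall synthesis in Gram-positive bacteria, or PBS by intraperitoneal injection, and colon was taken at zeitgeber time (ZT, hours from lights on) 5, 11, 17 or 23. This made 16 groups of 4 libraries. Deposited estimated counts totalled 10044032 to 13615804 per SPF library and 10513966 to 15736087 per GF library. Per its title, the study asks which effects of antibiotics on the gut immune response arise without the microbiota, and the GF mice address that question. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries.

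Marker genes showed how the libraries differed in makeup. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 32 SPF libraries and in 21 of the 32 GF libraries. They were lacking in 2 of 16 GF PBS libraries and in 9 of 16 GF vancomycin libraries (Fisher's exact test, two-sided, p = 0.0233, not adjusted). As a score, the Y-linked list differed by -2.21 log2 CPM between GF treatments (permutation p = 0.00794, adjusted p = 0.0556 over 14 score tests). Between SPF treatments it differed by 0.04 (adjusted p = 0.422). The mean log2 CPM of the B cell and lymphoid follicle list was 3.96 ± 1.32 (SD, n = 16) in SPF PBS and 4.70 ± 1.46 in SPF vancomycin libraries (difference 0.75, permutation p = 0.133, adjusted p = 0.408). In GF libraries it differed by -0.66 (permutation p = 0.424, adjusted p = 0.474). Colon position, scored as distal minus proximal Hox genes, differed by 0.25 between SPF treatments (permutation p = 0.193, adjusted p = 0.408) and by -1.01 between GF treatments (permutation p = 0.44, adjusted p = 0.474). Its SD was 0.71 in SPF PBS and 0.56 in SPF vancomycin libraries, against 3.19 in GF PBS and 4.20 in GF vancomycin libraries. The GF libraries thus varied far more in position.

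**Figure D1:**
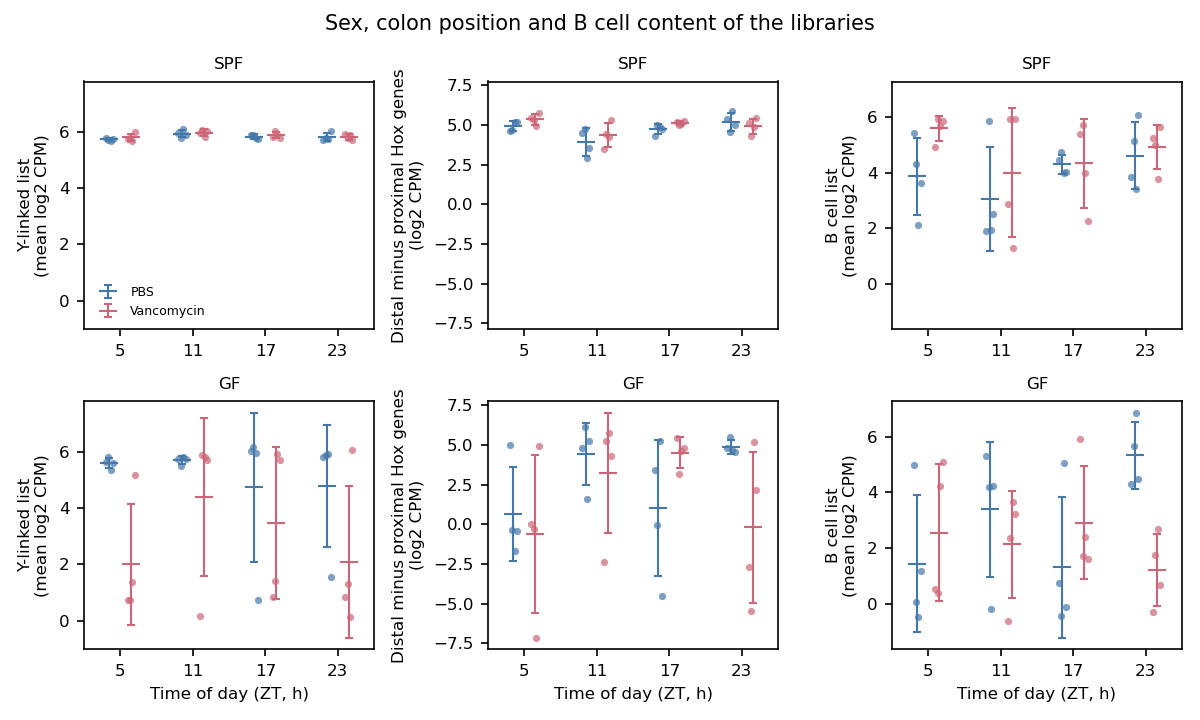
Y-linked list (mean log2 CPM), colon position score (distal minus proximal Hox genes, log2 CPM) and B cell list (mean log2 CPM) by time of day (ZT, h), SPF libraries in the top panels and GF libraries in the bottom panels. Each point is a library, bars are the mean of 4 libraries and error bars the SD, and Y-linked values fall apart into separate levels in GF libraries, with 9 of 16 vancomycin and 2 of 16 PBS libraries at the low level.

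In SPF mice, vancomycin changed 137 genes over all times (64 rose, 73 fell; edgeR, adjusted p under 0.05, 16 libraries per treatment). Cxcl9 (ENSMUSG00000029417), a chemokine that draws T cells, rose by a log2 fold change of 2.41 ± 0.45 (SE; adjusted p = 0.0154), from 1.01 ± 0.90 to 6.38 ± 7.05 CPM (SD, n = 16 each). Saa1 (ENSMUSG00000074115) and Saa2 (ENSMUSG00000057465), serum amyloid A proteins that colon epithelium makes in response to microbes, rose by 1.13 ± 0.19 (adjusted p = 0.0084) and 1.16 ± 0.22 (adjusted p = 0.0154). Saa1 went from 958 ± 252 to 2204 ± 1225 CPM. Oas2, an interferon-induced sensor of double-stranded RNA, rose by 1.68 ± 0.36 (adjusted p = 0.0264), from 4.72 ± 2.73 to 17.2 ± 16.5 CPM.

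Of 41 interferon-stimulated genes tested in SPF mice, 9 rose, and 32 rose when adjusted over the list alone. Their median log2 fold change was 0.66, and 38 of the 41 were positive. Among them were Gbp2 (1.02 ± 0.22, adjusted p = 0.0264; 34.8 to 72.1 CPM), Igtp (0.99 ± 0.21, adjusted p = 0.028) and Iigp1 (1.29 ± 0.30, adjusted p = 0.0372), GTPases that act against pathogens inside cells. Usp18, a brake on interferon signalling, rose by 1.04 ± 0.24 (adjusted p = 0.0339). Of 13 genes of MHC class I and antigen processing, 3 rose and 9 when adjusted over the list alone: H2-D1 (0.34 ± 0.07, adjusted p = 0.0245; 1381 to 1761 CPM), Psmb10, an immunoproteasome subunit (0.37 ± 0.06, adjusted p = 0.0084), and Psme1, a proteasome activator (0.30 ± 0.06, adjusted p = 0.0181). B2m had a value of 0.31 ± 0.08 (adjusted p = 0.0525). Of 32 genes of pattern recognition and NF-kB signalling, none passed over all genes in edgeR, 14 had an unadjusted p under 0.05, DESeq2 called 4, and 6 rose when adjusted over the list alone. Relb (0.30 ± 0.08, adjusted p = 0.0611) and Sigirr (0.27 ± 0.07, adjusted p = 0.0555) had its smallest p.

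These 3 lists passed camera and fry. Camera gave adjusted p = 2.16e-21 for interferon-stimulated genes, 2.34e-09 for MHC class I and 3.38e-06 for pattern recognition, and fry gave 0.0258, 0.00574 and 0.00574. With an estimated correlation the adjusted p was 0.23, 0.103 and 0.103. None of the 3 passed fry with a T and NK cell covariate (adjusted p = 0.173, 0.0618 and 0.0618, with medians of 0.51, 0.20 and 0.13 in place of 0.66, 0.31 and 0.17) or with a macrophage and dendritic cell covariate (0.109, 0.0577 and 0.0577), both chosen after the data were seen. A B cell or a smooth muscle covariate ended the fry call of the interferon list alone (0.0817 and 0.053). Immune cell marker lists lay higher beside them in camera. All 25 T and NK cell genes were positive (median 0.80, adjusted p = 5.92e-08), with Cd3d, part of the T cell receptor complex, past the threshold both ways of adjusting, among all genes and adjusted over the list alone (1.92 ± 0.46, adjusted p = 0.0428; 4.45 to 14.04 CPM). All 20 B cell and follicle genes were positive (median 0.76, adjusted p = 1.09e-05), 9 of 10 MHC class II genes (median 0.70, adjusted p = 2.97e-04) and all 22 macrophage and dendritic cell genes (median 0.29, adjusted p = 7.02e-05; 1 rose adjusted over the list alone). Each of these 4 lists had an adjusted p = 0.673 with an estimated correlation, and fry gave adjusted p from 0.266 to 0.39. In the B cell and MHC class II lists no gene passed in edgeR or DESeq2, and 1 and 4 had an unadjusted p under 0.05. H2-Ab1, an MHC class II chain, had a value of 0.71 ± 0.28 (adjusted p = 0.212).

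**Figure D2:**
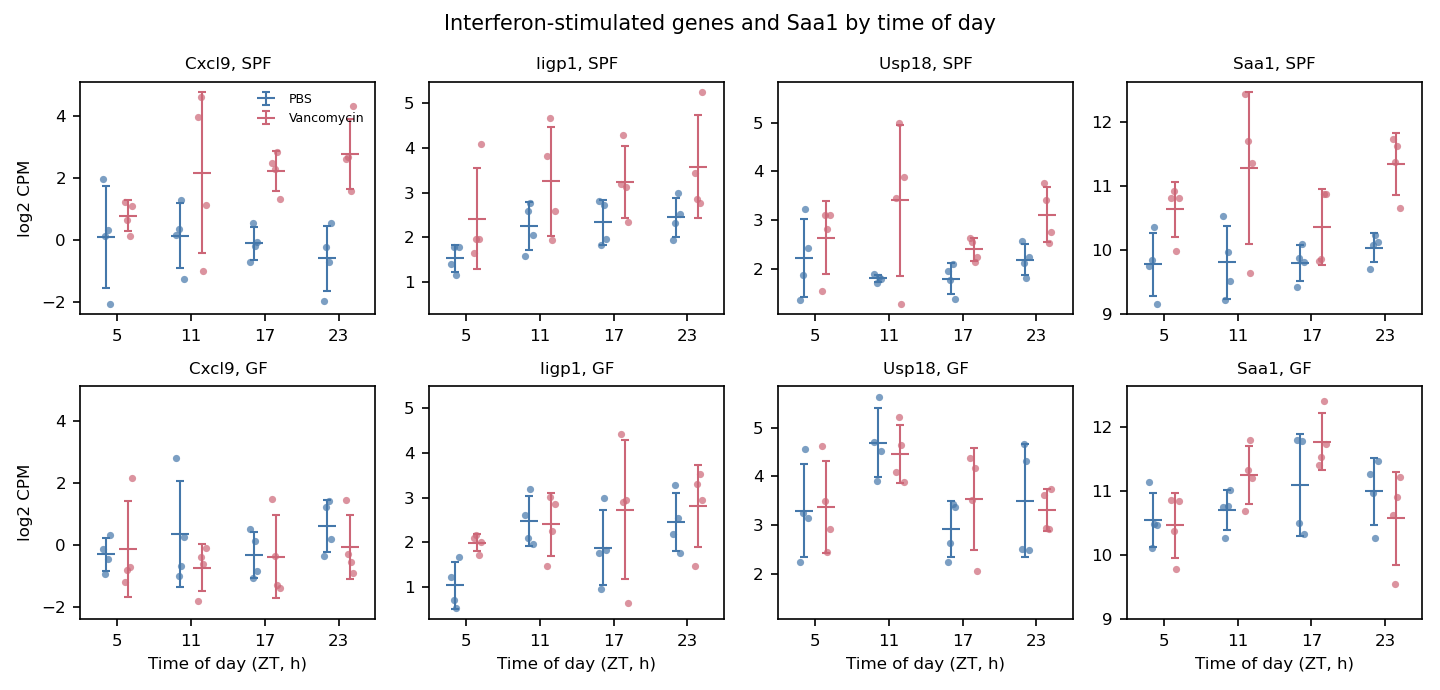
Log2 CPM of Cxcl9, Iigp1, Usp18 and Saa1 by time of day (ZT, h) in SPF (top) and GF (bottom) colon, PBS in blue and vancomycin in red, with each point a library, bars the mean and error bars the SD of 4 libraries. Over all times vancomycin raised these genes in SPF mice (Cxcl9 by a log2 fold change of 2.41, Saa1 by 1.13), while GF values were -0.34 ± 0.47 and 0.18 ± 0.18 (SE). Iigp1 also had a positive GF value, and edgeR called 0 genes for the difference between the SPF and GF effects.

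Of the 30 colonocyte genes tested in SPF mice, 4 rose and 1 fell, and adjusted over the list alone 6 rose and 8 fell. Scnn1b (ENSMUSG00000030873) and Scnn1g, subunits of the epithelial sodium channel that aldosterone controls, rose by 1.54 ± 0.31 (adjusted p = 0.019; 11.1 ± 11.4 to 25.95 ± 15.3 CPM) and 2.29 ± 0.52 (adjusted p = 0.0339; 3.71 to 11.6 CPM). Hsd11b2 (ENSMUSG00000031891), the enzyme that inactivates glucocorticoids and so leaves the mineralocorticoid receptor to aldosterone, rose by 0.91 ± 0.19 (adjusted p = 0.0222; 194 to 358 CPM). Slc5a8, a transporter of short-chain fatty acids, fell (-0.47 ± 0.11, adjusted p = 0.0391; 324 to 236 CPM), and is named here after its value was seen. Saa1 is the other member that rose. The list's median was -0.10, its mean 0.06 and its mixed fry p = 3.41e-06 (n = 16 libraries per treatment). Slc7a9, a cystine and basic amino acid transporter that was also chosen after its value was seen, rose by 2.24 ± 0.39 (adjusted p = 0.0084).

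Genes that fell in SPF mice included Celf5 (ENSMUSG00000034818), an RNA-binding protein of neurons, with the smallest p of all genes (-0.77 ± 0.11, adjusted p = 0.0022; 11.2 ± 1.96 to 6.80 ± 2.33 CPM). Linker histone H1f4 (-0.93 ± 0.19, adjusted p = 0.0222; 5.82 to 3.00 CPM), core histone H4c18 (-0.85 ± 0.20, adjusted p = 0.0347) and Nccrp1 (-0.87 ± 0.17, adjusted p = 0.019; 19.4 to 9.91 CPM) fell, as did Nkain2 (-1.67 ± 0.37, adjusted p = 0.0337) and Nyap1 (-0.80 ± 0.16, adjusted p = 0.019). Thrsp, a regulator of fat synthesis, fell (-1.33 ± 0.30, adjusted p = 0.0339), and Efna3, an ephrin ligand, fell (-0.73 ± 0.18, adjusted p = 0.0441), while Orc1, of the replication origin complex, rose (2.24 ± 0.53, adjusted p = 0.042). Among 34 epithelial antimicrobial genes 3 rose (Saa1, Saa2 and Pglyrp1, a peptidoglycan-binding protein, 0.31 ± 0.07, adjusted p = 0.0339) and 1 fell (Gsdmc3, a gasdermin, -0.55 ± 0.13, adjusted p = 0.042). Adjusted over the list alone 3 rose and 7 fell. The antimicrobial lectin Reg3g had a value of 0.00 (adjusted p = 1.00), Reg3b 0.36 ± 1.12 (0.92), Retnlb -0.23 ± 0.25 (0.701), the mucin Muc2 -0.14 ± 0.18 (0.764; 4696 to 4122 CPM) and the IgA heavy chain Igha -0.54 ± 0.24 (0.263). No SE is given for Reg3g, because its value is near 0. Its level varied widely, at 7.29 log2 CPM in SPF PBS ZT17 replicate 4 and -1.46 to -0.49 in the others of that group.

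Metabolic and structural lists lay lower in SPF mice in camera alone. Of 100 random splits of the SPF libraries, 20 gave 15 camera lists or more, so chance is not excluded for the count. Fatty acid oxidation had 2 of 30 genes that fell, Cpt1a, the carnitine acyltransferase that admits fatty acids to mitochondria (-0.30 ± 0.07, adjusted p = 0.0457), and Acads (-0.32 ± 0.08, adjusted p = 0.0467), and 3 that fell adjusted over the list alone (median -0.07, camera adjusted p = 9.55e-04). Xenobiotic metabolism had 1 of 45, the cytochrome Cyp2s1 (-0.56 ± 0.10, adjusted p = 0.0154; 113 to 77.1 CPM), and adjusted over the list alone 1 rose and 4 fell (median -0.18, camera adjusted p = 2.97e-04). The crypt stem cell list had 1 of 15 either way, the Wnt target Axin2 (-0.31 ± 0.08, adjusted p = 0.0432; median -0.09, camera adjusted p = 0.0112). The list of interstitial cells, neurons and glia had 1 of 23, Ano1, the chloride channel of pacemaker cells (-0.49 ± 0.11, adjusted p = 0.0339; median -0.18, camera adjusted p = 0.0161). Fibroblast (median -0.12, camera adjusted p = 0.00129), smooth muscle (-0.10, 0.00244) and adipose genes (-0.64, 0.00494) had no member past the threshold over all genes in edgeR, and 7 of 20, 5 of 19 and 6 of 16 at an unadjusted p under 0.05. DESeq2 called 1 in each, and adjusted over the list alone 4 fibroblast genes fell and 1 rose, and 1 smooth muscle and 1 adipose gene fell. Heat shock genes lay higher in camera (median 0.10, adjusted p = 0.0322), with 2 of 16 at an unadjusted p under 0.05. All 8 lists had an adjusted p = 0.673 with an estimated correlation.

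Single members of further lists changed in SPF mice. Herpud1 (0.35 ± 0.08, adjusted p = 0.0356) and Ddit4, an inhibitor of mTORC1 (0.61 ± 0.12, adjusted p = 0.0184; 90.7 to 142 CPM), rose among 25 genes of endoplasmic reticulum stress, both also adjusted over the list alone. Tsc22d3, a glucocorticoid target, rose (0.43 ± 0.09, adjusted p = 0.029) among 17 such genes, 4 of which rose adjusted over the list alone, and Fkbp5 had a value of 0.73 ± 0.18 (adjusted p = 0.0502). The bile acid list of 14 had Cyp27a1, a sterol hydroxylase, higher (0.69 ± 0.17, adjusted p = 0.0466) and the vitamin D receptor Vdr lower (-0.34 ± 0.08, adjusted p = 0.0482), with 3 higher and 4 lower adjusted over the list alone. Fos fell among 21 immediate early genes (-0.96 ± 0.23, adjusted p = 0.046; 150 to 71.9 CPM), and Ccl28, a chemokine that recruits plasma cells, among 24 cytokines (-0.32 ± 0.08, adjusted p = 0.042). Adjusted over the list alone 2 immediate early genes fell, and 2 cytokines rose and 1 fell. In edgeR no gene passed in the core clock (18 tested, median -0.08), proliferation (30, 0.05), goblet cell (26, -0.05), plasma cell (12, -0.20) and tight junction lists (18, -0.04), where 4, 0, 3, 4 and 3 genes had an unadjusted p under 0.05. DESeq2 called 1 goblet cell and 1 tight junction gene, and 1 tight junction gene fell adjusted over the list alone.

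Only 12 of the 32 libraries left the SPF count within 1.5 times when left out: without Vancomycin ZT5 replicate 4 it was 47 and without Vancomycin ZT11 replicate 3 it was 518. DESeq2 called 493 genes, 135 of them among the 137, and with a B cell covariate, a colon position covariate or a Y-linked covariate 72, 71 and 55 genes were called. All 32 SPF libraries had Y-linked expression, with an SD of 0.12 log2 CPM in each treatment, so that covariate does not stand for sex here. Of the genes named for this effect, Celf5, Saa1, Scnn1b, Hsd11b2, H1f4, Nccrp1, Cyp2s1 and Ddit4 kept their call in all 49 alternatives. Cxcl9, Saa2, Nyap1, Psmb10, Psme1 and H2-D1 kept theirs without each of the 32 libraries. Left out one at a time, 1 to 7 of the 32 libraries ended the call of Gbp2, Oas2, Igtp, Nkain2 and Tsc22d3. For Pglyrp1, Thrsp, Usp18, Scnn1g, Herpud1, Ano1, H4c18 and Iigp1 it was 11 to 17. The call was lost in 20 to 25 of the 32 fits for Orc1, Efna3, Gsdmc3, Cd3d, Ccl28, Vdr, Fos, Axin2, Cpt1a, Cyp27a1 and Acads.

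At single times, with 4 libraries per group, 14 genes at ZT5 (3 higher, 11 lower) and 54 at ZT17 (22 higher, 32 lower) differed between vancomycin and PBS in SPF mice. For the ZT5 count chance was not excluded, as 2 of 35 splits of the libraries gave 14 genes or more (highest other 44). At ZT5 Ttll4 (1.06 ± 0.19, adjusted p = 0.0228; 18.4 to 38.2 CPM), the formin Fhod1 (0.77 ± 0.13, adjusted p = 0.0189) and the transcription factor Rfx1 (0.40 ± 0.08, adjusted p = 0.0303) rose. Palm, a membrane protein of the paralemmin family, fell (-1.20 ± 0.17, adjusted p = 0.00265; 37.3 ± 2.29 to 16.2 ± 2.30 CPM), with the G protein subunit Gnb5 (-1.34 ± 0.27, adjusted p = 0.037) and Csdc2 (-1.25 ± 0.23, adjusted p = 0.0268). Smooth muscle genes also lay lower at ZT5 (median -0.58, camera adjusted p = 1.38e-10, fry adjusted p = 0.297, 0.604 with an estimated correlation). Their library score was 8.63 to 8.82 log2 CPM after vancomycin and 9.20 to 9.43 after PBS. Smooth muscle and B cell covariates lowered the ZT5 count, as given below, so tissue makeup was not separated from treatment. Palm kept its call in all 25 alternatives. At ZT17 the interferon-inducible Ifi27l2b rose by 2.66 ± 0.43 (adjusted p = 0.00288; 13.7 ± 2.11 to 87.0 ± 27.8 CPM), Zbtb38 by 2.396 ± 0.39 (adjusted p = 0.00288; 43.3 to 228 CPM) and the collagen Col8a1 by 1.90 ± 0.31 (adjusted p = 0.00304). Mptx2, a pentraxin, and Itln1, an intestinal lectin, fell at ZT17 (-10.35 ± 2.20, adjusted p = 0.0303, and -8.47 ± 1.70, adjusted p = 0.0196), from 286 ± 460 to 0.211 CPM and from 782 ± 1206 to 2.19 CPM. Both calls were lost in 11 of 25 alternatives, and over all 25 the values ranged from -11.6 to -6.58 for Mptx2 and from -8.89 to -5.48 for Itln1. Among the 11 were 5 of 8 fits without 1 library, those without PBS ZT17 replicate 1 or any 1 of the 4 Vancomycin ZT17 libraries, with adjusted p up to 0.133 for Mptx2 and 0.1 for Itln1. Of the ZT5 genes, Palm kept its call without each of the 8 libraries, while Ttll4, Rfx1 and Csdc2 lost it in 5 of the 8 fits, Gnb5 in 6 and Fhod1 in 3, with adjusted p up to 0.171. The inflammasome sensor Nlrp1b was lower at ZT17 (-4.46 ± 0.64, adjusted p = 6.84e-04; 8.95 to 0.399 CPM). Nlrp1b, Ifi27l2b and Col8a1 also passed the treatment by time test below. Of the placed ZT17 genes, 13 of 53 lay within 10 tested genes of another (random 95th percentile 8, permutation p = 8e-04). The labels give no cage or litter, so inherited variation shared within a group was not separated from vancomycin at ZT17.

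At SPF ZT11 and ZT23 edgeR called 0 genes, with 1670 and 1243 at an unadjusted p under 0.05, and DESeq2 called 102 and 42. The smallest p at ZT11 belonged to Col8a1 (-1.62 ± 0.31), the interferon-inducible Trim12c (1.86 ± 0.36), Galt (0.56 ± 0.11) and Igkv2-109 (-3.54 ± 0.68), all at adjusted p = 0.0739. At ZT23 Trim5 (2.53 ± 0.45), Pcnx4 (-0.66 ± 0.12) and Celf5 (-1.15 ± 0.22) had adjusted p = 0.0899 and H1f3 (-1.93 ± 0.39) 0.125. DESeq2 called 240 genes at ZT5 and 147 at ZT17. The count at ZT5 was 1 without PBS ZT5 replicate 2 or Vancomycin ZT5 replicate 4 and 88 without PBS ZT5 replicate 4, that at ZT11 was 109 without Vancomycin ZT11 replicate 3, and that at ZT17 was 21 without Vancomycin ZT17 replicate 1.

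The treatment by time test asks whether the vancomycin difference depended on the hour, and 61 genes passed it in SPF mice. Hsd17b13, a lipid droplet protein, had the smallest p (adjusted p = 7.17e-04), with 60.8, 13.7, 63.6 and 47.4 CPM at ZT5, 11, 17 and 23 after PBS and 47.7, 55.3, 3.56 and 79.1 CPM after vancomycin. Col8a1 (adjusted p = 7.69e-04) peaked at ZT11 after PBS (48.5 CPM) and at ZT17 after vancomycin (30.3 CPM). Ifi27l2b (adjusted p = 0.00219) was highest at ZT11 after PBS (61.1 CPM) and at ZT17 after vancomycin (87.0 CPM). Nlrp1b (adjusted p = 0.00137) was at 1.69 CPM at ZT11 and 8.95 CPM at ZT17 after PBS, against 6.18 and 0.399 CPM after vancomycin. Trim12c (adjusted p = 0.00186) was at 12.3 and 44.7 CPM at those hours after PBS and at 44.8 and 12.8 CPM after vancomycin, and the calcium sensor Stim1 (adjusted p = 0.00186) at 88.0 and 189 CPM against 118 and 93.8 CPM. Of the 61 genes, 2 were also called in the effect over all times (0.493 expected by chance, Fisher's exact p = 0.0873). DESeq2 called 205 genes.

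**Figure D3:**
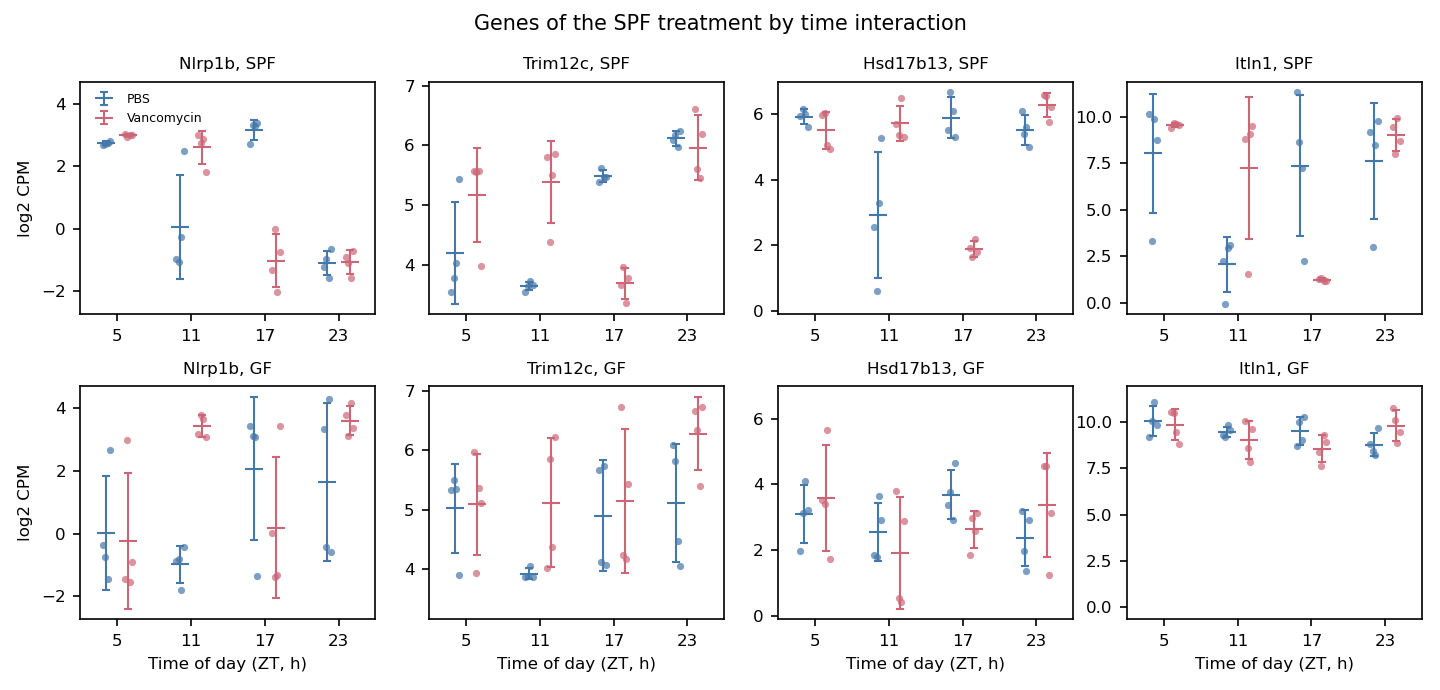
Log2 CPM of Nlrp1b, Trim12c, Hsd17b13 and Itln1 by time of day (ZT, h) in SPF (top) and GF (bottom) colon, PBS in blue and vancomycin in red, with each point a library, bars the mean and error bars the SD of 4 libraries. Nlrp1b at ZT17 was at 8.95 ± 1.77 CPM in SPF PBS libraries and at 0.399 CPM in SPF vancomycin libraries, whereas among GF PBS libraries 1 was at 0.245 CPM and the others at 8.38 to 10.7 CPM.

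Time of day changed 1507 genes in SPF mice given PBS and 1389 in SPF mice given vancomycin, with 635 in both lists (124 expected by chance). Nr1d1 (ENSMUSG00000020889), a repressor of the clock, ran from 6.04 CPM at ZT5 to 122, 179 and 24.02 CPM at ZT11, 17 and 23 after PBS (adjusted p = 4.81e-11), and over 10, 57.7, 110 and 27.1 CPM after vancomycin (adjusted p = 1.55e-07). Dbp (ENSMUSG00000059824), a clock output factor, reached 153 CPM at ZT17 after PBS (adjusted p = 4.17e-06) and 124 CPM after vancomycin (adjusted p = 4.80e-06). Nr1d2 passed in both (adjusted p = 5.72e-10 and 1.74e-07). Arntl, which encodes the clock activator BMAL1, ran in the opposite phase, at 64.6 CPM at ZT5 and 15.7 CPM at ZT17 after vancomycin (adjusted p = 7.49e-06), and at 72.1 and 19.5 CPM after PBS. Beside the clock, Col8a1 (adjusted p = 1.72e-07), Tmc8 (3.79e-06) and Stim1 (1.60e-05) varied with time after PBS, and the thyroid hormone receptor Thra (1.47e-05) and Nlrp1b (2.46e-05) after vancomycin. Col8a1, Stim1 and Nlrp1b also passed the treatment by time test, so their course differed between treatments. Of the 61 genes of that test, 47 were among the 1507 (5.43 expected by chance), and both tests used the PBS libraries. Variation between cages or litters shared within a group was not separated from time of day. Smooth muscle and colon position covariates lowered the time-of-day counts to 305 and 352 genes after PBS and to 314 and 740 after vancomycin, and a Y-linked covariate gave 887 after vancomycin. DESeq2 raised them to 2639 after PBS and 2254 after vancomycin, and limma with array weights to 3454 and 1803. Without PBS ZT11 replicate 3 or 4 the PBS count was 671 or 839, and without Vancomycin ZT11 replicate 1 the vancomycin count was 798.

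**Figure D4:**
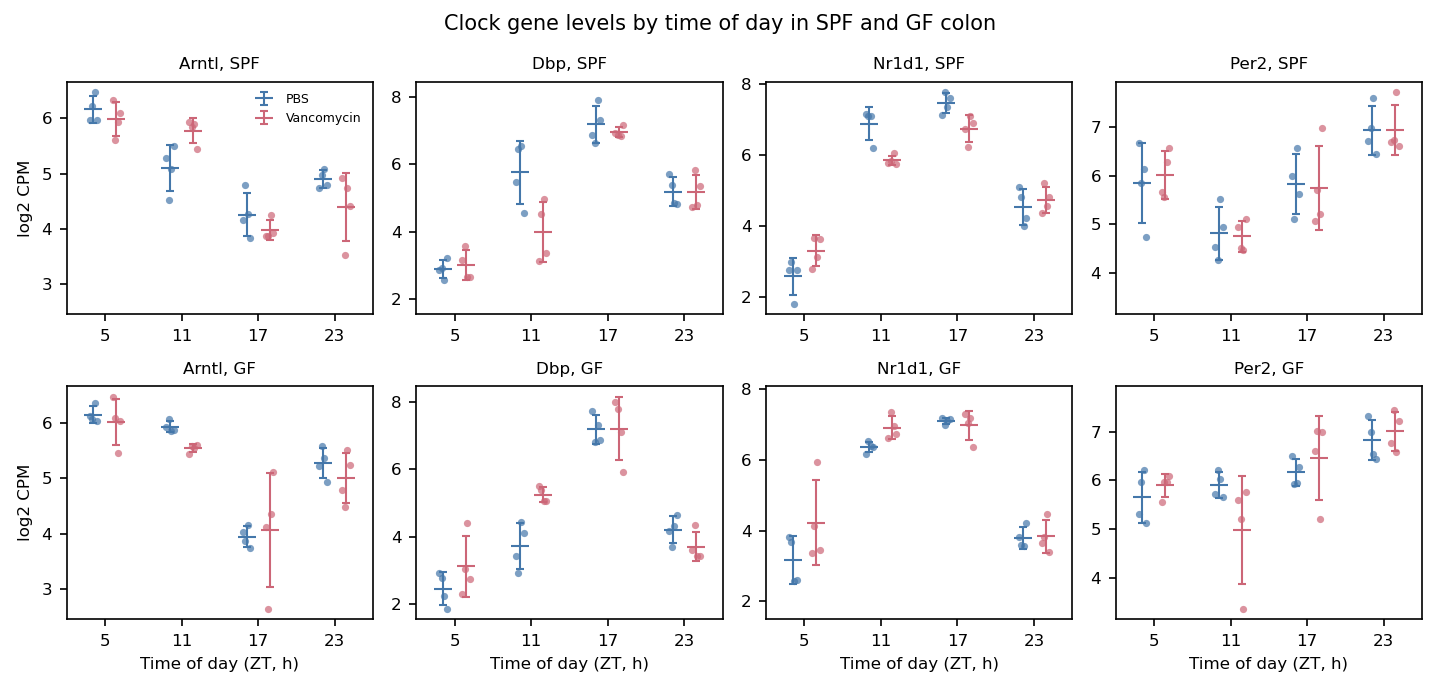
Log2 CPM of the clock genes Arntl, Dbp, Nr1d1 and Per2 by time of day (ZT, h) in SPF (top) and GF (bottom) colon, PBS in blue and vancomycin in red, with each point a library, bars the mean and error bars the SD of 4 libraries. Nr1d1 in SPF PBS libraries rises from 6.04 CPM at ZT5 to 179 CPM at ZT17, and Arntl falls from 72.1 to 19.5 CPM.

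In GF mice, edgeR called 0 genes for vancomycin over all times, with 672 at an unadjusted p under 0.05, and DESeq2 called 5, all predicted genes with a log2 fold change beyond 10 in size, named after their values were seen: Gm49450 (-10.9), Gm12669 (-10.9), Gm44502 (-11.1), Gm28661 (12.2) and Gm28439 (-12.3). Genes that passed in SPF mice had GF values of 0.34 ± 0.40 for Oas2, 0.64 ± 0.28 for Iigp1, 0.03 ± 0.28 for Usp18, -0.34 ± 0.47 for Cxcl9, 0.18 ± 0.18 for Saa1 (1953 ± 781 to 2317 ± 1153 CPM), -0.10 ± 0.24 for Scnn1b and -0.03 ± 0.18 for both Hsd11b2 and Celf5 (all at adjusted p = 1.00). The smallest p belonged to Ighv1-69 (-3.83 ± 0.86; 0.582 to 0.0461 CPM), Zfp790 (-0.37 ± 0.09), Gm47154 (-1.66 ± 0.41) and Etfrf1 (0.22 ± 0.05). Reg3g (0.80 ± 0.67), Reg3b (2.16 ± 1.27), Retnlb (0.39 ± 0.66), Muc2 (-0.13 ± 0.25), H2-Ab1 (-0.29 ± 0.43) and Igha (-0.63 ± 0.43) also had adjusted p = 1.00. Colon position varied more among GF than among SPF libraries, which may hide changes. With a position covariate edgeR still called 0 genes for the GF effect. Y-linked expression was also unbalanced, lacking in 9 of 16 GF vancomycin and 2 of 16 GF PBS libraries. With a Y-linked covariate edgeR called 0 genes too. Sex, as far as Y-linked expression marks it, was thus not fully separated from vancomycin in GF mice.

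Gene groups in GF mice lay apart from other genes in camera alone, with no member past the threshold in edgeR or DESeq2. Of 100 random splits of the GF libraries, 69 gave 11 camera lists or more, so chance is not excluded for the count. Cholesterol biosynthesis was lower, with all 25 genes negative (median -0.22, camera adjusted p = 4.06e-15; adjusted p = 0.489 with an estimated correlation; fry p = 0.0394, adjusted p = 0.711). Its members Nsdhl (-0.34 ± 0.11), Acat2 (-0.34 ± 0.11), Fdps (-0.41 ± 0.14) and Mvk (-0.26 ± 0.09) had the smallest p, and 9 of 25 had an unadjusted p under 0.05. Proliferation genes were lower, 1 of 30 positive (median -0.23, camera adjusted p = 1.16e-10; adjusted p = 0.558 with an estimated correlation), among them Cenpf (-0.43 ± 0.13), a kinetochore protein. All 20 B cell genes (median -1.04, camera adjusted p = 4.87e-04) and all 11 plasma cell genes (-0.36, 0.00147) were negative, as was the Y-linked list (-1.14, 2.47e-05), with adjusted p = 0.863, 0.489 and 0.269 with an estimated correlation. The Y-linked value goes with the 9 of 16 vancomycin and 2 of 16 PBS libraries that lacked Y-linked expression. Interferon-stimulated genes were slightly higher (median 0.19, camera adjusted p = 8.22e-05; adjusted p = 0.855 with an estimated correlation; 36 of 41 positive). Mesothelium (0.72, 1.51e-06), adipose (0.67, 1.25e-05) and erythrocyte genes (0.44, 0.0129) were higher, with Muc16 at 1.46 ± 0.52, Msln at 0.63 ± 0.24, Fabp4 at 1.01 ± 0.41 and Adipoq at 1.67 ± 0.72 (adjusted p = 0.489, 0.558 and 0.558 with an estimated correlation). Heat shock (-0.06, 0.0186) and ribosomal protein genes (-0.06, 0.00833) were lower, at adjusted p = 0.764 and 0.869 with an estimated correlation. Adjusted over the list alone, Mt1 (0.40 ± 0.11) and Mt2 (0.63 ± 0.18), metallothioneins that bind zinc, rose within the glucocorticoid list, and 1 squamous epithelium gene fell.

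At ZT5, 11, 17 and 23 edgeR called 0 genes in GF mice at each time, with 606, 832, 757 and 2050 at an unadjusted p under 0.05, and DESeq2 called 9, 8, 13 and 55. The smallest p were those of Fam220a at ZT5 (6.72 ± 1.45, adjusted p = 1.00), Faf1 (0.94 ± 0.19) and the zinc transporter Slc39a7 (-0.68 ± 0.14) at ZT11 (adjusted p = 0.326), Csf2ra (1.01 ± 0.23) at ZT17 beside the predicted gene Gm47154 (-6.85 ± 1.13, adjusted p = 0.0534), and Trim30b at ZT23 (-4.63 ± 0.80, adjusted p = 0.0677). The treatment by time test called 0 genes (1405 at an unadjusted p under 0.05, DESeq2 9), with Nfyc first (adjusted p = 0.528).

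Time of day changed 24 genes in GF mice given PBS and 24 in those given vancomycin, 15 of them in both lists (0.034 expected by chance; Fisher's exact p = 8.17e-40). Clock genes had the smallest p. Ciart rose from 1.61 CPM at ZT5 to 39.0 CPM at ZT17 after PBS (adjusted p = 2.21e-07; 4.00e-08 after vancomycin), Dbp from 5.54 to 150 CPM (2.21e-07 and 1.99e-06), and Nr1d1 from 9.55 to 138 CPM (2.90e-06 and 6.95e-05). Per3 passed in both (adjusted p = 9.84e-06 and 1.90e-05), Nfil3 (1.51e-05) and Mt2 (1.46e-04) after PBS, and Per1 (1.03e-04) and Coq10b (3.81e-04) after vancomycin. Of the 24 genes after PBS, 16 were also called in SPF mice given PBS (2.15 expected by chance, Fisher's exact p = 5.83e-12), and after vancomycin 19 of 24 (1.98 expected, p = 6.66e-17). DESeq2 called 403 and 179 genes and limma with array weights 2734 and 358. With GF libraries that have Y-linked expression alone, a choice made after the data were seen, 18 genes were called after PBS, 15 of them among the 24. After vancomycin 4 were called, 2 of them among the 24. Dbp (adjusted p = 0.0666), Per3 (0.135), Per1 (0.253) and Coq10b (0.135) then lost their call after vancomycin. Without PBS ZT23 replicate 4 or ZT17 replicate 1 the PBS count was 66 or 15, and without Vancomycin ZT11 replicate 1, ZT17 replicate 4 or ZT17 replicate 1 the vancomycin count was 69, 39 or 14.

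The test of whether the vancomycin effect itself differed between SPF and GF mice called 0 genes in edgeR over 16604 genes, with 1651 at an unadjusted p under 0.05. The smallest p belonged to linker histone H1f2 (SPF minus GF -0.69 ± 0.14, adjusted p = 0.165; -0.53 in SPF and 0.16 in GF mice), Slc7a9 (2.01 ± 0.45), the kinesin Kifc2 (-0.76 ± 0.17) and Scnn1b (1.65 ± 0.39), the last 3 at adjusted p = 0.229. Cxcl9 (2.75 ± 0.67), Saa1 (0.95 ± 0.27), Scnn1g (2.46 ± 0.64), Hsd11b2 (0.94 ± 0.26) and H1f4 (-1.08 ± 0.27) had adjusted p = 0.229 too, Celf5 (-0.74 ± 0.22) 0.253, Saa2 (0.88 ± 0.30) 0.387 and Oas2 (1.34 ± 0.55) 0.434. DESeq2 called 16 genes, among them H1f2 (adjusted p = 4.89e-03), Slc7a9 (0.0114), Kifc2, Cxcl9 and Scnn1b (each 0.0293), Cd3d (0.0419) and Tsc22d3 (0.0471). The response of these genes in SPF mice was not shown by edgeR to differ from that in GF mice. Y-linked expression was unbalanced between treatments in GF libraries alone. Sex, as far as it is marked by these genes, was therefore not separated from vancomycin in this difference.

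By camera 18 lists differed between SPF and GF effects, and none did with an estimated correlation or by fry. Of 60 random splits 7 gave 18 lists or more, so chance is not excluded for the count. T and NK cell (median difference 1.51, adjusted p = 3.18e-08; adjusted p = 0.531 with an estimated correlation), B cell (1.66, 1.45e-07; 0.531) and interferon-stimulated genes (0.45, 5.73e-07; 0.531) lay higher in SPF mice, with 4, 0 and 1 members past the threshold adjusted over the list alone and 10, 12 and 9 at an unadjusted p under 0.05. Adipose (-1.30, 1.03e-06; 0.531) and mesothelium genes (-1.47, 1.66e-04) lay lower, 11 and 7 of them adjusted over the list alone. Pattern recognition genes (0.18, 4.16e-05) and Y-linked genes (1.13, 2.57e-04) had adjusted p = 0.249 with an estimated correlation and 0.0942 by fry. Across the 16604 genes the SPF and GF fold changes had a Pearson r of -0.141 and a Spearman rho of -0.134, genes not being independent replicates, and 59 and 65 of 100 relabellings of the GF libraries gave values as large. Of 136 genes called in SPF mice and tested in both, 67 had the same sign in GF mice.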

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

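Among the tests in this part, those of the spread in GF mice, of libraries exchanged in time, of the clock index and its difference between SPF and GF mice, and the T and NK cell and macrophage covariates were chosen after the results had been seen. Predictions for the T and NK cell covariate and for the other tests were written before their results were known.

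Of 240 combinations of a group of 4 libraries and a value, 12 had 1 library far from the other 3, and chance alone gives about 12. Library totals were low in GF PBS ZT17 replicate 3 (10.51 M estimated counts, the others 12.92 to 13.23 M) and GF Vancomycin ZT5 replicate 2 (12.07 M, the others 14.68 to 14.89 M). SPF PBS ZT11 replicate 2 had a B cell score of 5.83 log2 CPM, the others 1.92 to 2.53. SPF PBS ZT17 replicate 4 stood out in the antimicrobial lectins Reg3g (7.29 log2 CPM, the others -1.46 to -0.49) and Reg3b (7.51, the others -3.32 to -1.86), as GF Vancomycin ZT11 replicate 1 did in Reg3b (2.92, the others -3.32 to -2.50). H2-Ab1 was high in GF PBS ZT17 replicate 3 (7.30, the others 3.98 to 4.38) and low in SPF Vancomycin ZT23 replicate 3 (6.94, the others 7.78 to 7.91), which also had a Per2 of 7.71 (the others 6.61 to 6.73). Saa1 was low in SPF Vancomycin ZT5 replicate 3 (9.98, the others 10.81 to 10.92), Arntl in SPF Vancomycin ZT11 replicate 4 (5.44, the others 5.85 to 5.93) and Nr1d1 in SPF PBS ZT11 replicate 4 (6.19, the others 7.09 to 7.14).

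The vancomycin difference depended on the time of day for 61 genes in SPF mice, and of 100 splits of the libraries 1, the real one, gave as many (highest other 6). Taken singly, without adjustment over the split tests, this argues against a random split but not against cages or litters shared within a group. For Nlrp1b, Trim12c, Col8a1 and Ifi27l2b, PBS libraries at ZT11 resembled vancomycin libraries at ZT17, but the clock index of the libraries labelled vancomycin ZT17 averaged 1.588 (1.10 to 1.93), near PBS ZT17 (1.64) and above every PBS ZT11 library (at most 0.67), which argues against an exchange in time. Swiss Webster mice are outbred, and a candidate explanation is inherited variation shared by cage mates or littermates: 16 of 60 placed genes, such as Stim1 and Trim68 or Pgd and Nmnat1, lay within 10 tested genes of another (random sets: median 4, 95th percentile 8, highest 17; permutation p = 4e-04). Their spread within GF groups was high, at a median percentile of 82.2 among genes of like level, though other called sets also reached 69.6 to 82.2, sets led by clock genes in GF mice also lay near one another (permutation p = 0.0345 and 0.0381), and neighbouring genes may be regulated together. The labels give no cage or litter, so a vancomycin effect at particular hours stays open.

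Interferon-stimulated genes had a median log2 fold change of 0.66 after vancomycin in SPF mice (quartiles 0.39 to 0.99, 38 of 41 positive), and without any 1 of the 32 libraries it stayed between 0.556 (without Vancomycin ZT5 replicate 4) and 0.75 (without PBS ZT5 replicate 3), which argues against a single library. More lymphoid tissue was weighed because its abundant genes were also higher (Ighm from 66.0 to 117 CPM and Cd79a from 49.7 to 84.8 CPM of the B cell list, Trbc2 from 8.70 to 18.2 CPM of the T cell list). With a B cell covariate the median was 0.5365 (quartiles 0.33 to 0.84, fry p = 0.0057) and with a T and NK cell covariate 0.5056 (0.28 to 0.78, fry p = 0.0121; n = 16 libraries per treatment), so neither score alone took up the whole rise. These covariates were list means of the same libraries, entered 1 at a time, and may adjust only in part, so such cells as the whole cause are not excluded. As the fold shrank, the fry call over 43 lists ended (adjusted p = 0.0817 and 0.173, and 0.109 with a macrophage and dendritic cell covariate, at a median of 0.54). Without a covariate, the list's library score was 0.63 log2 CPM higher after vancomycin in SPF mice (permutation p = 0.00113, adjusted p = 0.0158 over the score tests). With the B cell, T and NK cell or macrophage and dendritic cell covariate, 40 of the 41 genes were positive in each fit. The lost calls thus went with a smaller fold, not with a turn of direction. Part of the rise may come with these cells, and all of it is not excluded, as the covariates may adjust only in part. The pattern is not called kept. A response to the antibiotic or to the microbes it removes stays a hypothesis that was not tested.

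At ZT11 the clock index was lower after vancomycin than after PBS in SPF mice (-1.42, exact p = 0.0857) and higher in GF mice (0.83, exact p = 0.0286), both at adjusted p = 0.171, with 4 libraries per group. The SPF effect minus the GF effect was -2.25 (permutation p = 0.00163 over 4900 relabellings), but the index and ZT11 out of 4 times were picked after the values were seen, so this p restates the observation and the same effect in both stays open. An offset in collection hour or clock phase at ZT11 could account for this difference, and would carry other time-of-day genes along. Over 611 such genes outside the clock list, the ZT11 effect was correlated across genes with the time course of the other table. The correlation was 0.0174 in SPF and 0.0197 in GF mice, inside the range of 70 relabellings (largest other 0.139 and 0.107). An offset was predicted to make it negative in SPF and positive in GF mice, beyond most relabellings, and neither value met this. The SPF value went against the predicted sign. Values inside the range of relabellings do not exclude a small offset, so an offset and a vancomycin effect on the clock were not told apart.

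By camera, 18 gene lists differed between the SPF and GF effects, but none did with an estimated correlation (lowest adjusted p = 0.249) or by fry (lowest adjusted p = 0.0942), and 7 of 60 splits gave 18 or more (highest other 20), so chance is not excluded.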

How the results depend on the processing

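The DESeq2 results, limma with pseudocount 1, robust edgeR, scaling by library totals, the position covariate, GF libraries with Y-linked expression alone, the effect averaged over ZT5 and ZT23, at single times and in F tests array weights, covariates, a mean value filter, other scalings and limma with other pseudocounts than 5, and covariates for gene lists were chosen after seeing the data. The other alternatives were planned.

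The number of genes called depended on the setting more than the direction of the genes named. For every change below the cause was not tested, except that fits on 8 libraries and fits without some libraries rest on fewer samples. DESeq2 called 493 genes for the SPF effect, 240, 102, 147 and 42 at ZT5, 11, 17 and 23, 205 for the SPF interaction, and 2639 and 2254 for time of day after PBS and vancomycin. In GF mice it called 5, then 9, 8, 13 and 55 at the 4 times, 9 for the interaction, and 403 and 179 for time of day, and for the difference between SPF and GF 16. Array weights gave 432 for the SPF effect, 366, 5, 125 and 35 at the 4 times, 103 for the interaction and 3454 for time of day after PBS. In GF mice they gave 162, 2 and 2 at ZT11, 17 and 23, 4 for the interaction, 2734 and 358 for time of day, and 12 for the difference. No filter on low values gave 80 for the SPF effect (more genes are then adjusted for), a B cell covariate 72, a Y-linked covariate 55 and a colon position covariate 71. Limma with pseudocount 5 gave 7 at SPF ZT11, and fits on the 8 libraries of a time gave 8 at SPF ZT5, 1 at SPF ZT23 and 1 at GF ZT11. A smooth muscle covariate gave 305 and 314 for time of day in SPF mice after PBS and vancomycin, and 39 and 46 in GF mice, and the position covariate gave 352 and 740 in SPF mice. A Y-linked covariate gave 887 for time of day after vancomycin in SPF mice, a B cell covariate 50 after vancomycin in GF mice and library totals 38 after PBS in GF mice. At SPF ZT5 smooth muscle and B cell covariates gave 4 and 5. At SPF ZT11 limma with pseudocounts 0.5 and 1 gave 3 each, quantile normalization 12 and a B cell covariate 1, and at SPF ZT23 a B cell covariate gave 7 and library totals 4. These limma pseudocounts and quantile normalization each gave 1 at GF ZT17 and 1 at GF ZT23, and a smooth muscle covariate 1 at GF ZT17. With GF libraries that have Y-linked expression alone, 1 gene was called for the GF effect, 1 at ZT5, 1 for the interaction, 4 for time of day after vancomycin and 1 for the difference. Quantile normalization gave 2 for the difference and separate fits per table gave 1. Camera with an estimated correlation called 0 lists in SPF, GF and the difference, and fry 3, 0 and 0. With GF libraries that have Y-linked expression, camera called 7 lists in GF mice. With the difference averaged over ZT5 and ZT23 in the fit of all 32 libraries, edgeR called 162 genes for the SPF effect (49 higher, 113 lower), 65 of them among the 137, and 0 for the GF effect. Of the named genes, 50 passed in a test with a sign, and of their 2157 values under an alternative, libraries left out included, 1542 kept the call, 615 lost it and 0 turned sign. Tests of the interaction and of time of day have no sign.

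Leaving out 1 library gave 47 to 518 for the SPF effect, and 12 of 32 libraries left it within 1.5 times. It was 47 without Vancomycin ZT5 replicate 4, 85 without replicate 2, 59 and 85 without PBS ZT5 replicates 2 and 3, 64, 246 and 80 without PBS ZT11 replicates 1, 2 and 4, 83, 74, 518 and 88 without Vancomycin ZT11 replicates 1, 2, 3 and 4, 81 and 63 without PBS ZT17 replicates 3 and 4, 63 without Vancomycin ZT17 replicate 2, 84, 58, 60 and 206 without PBS ZT23 replicates 1 to 4, and 55 and 81 without Vancomycin ZT23 replicates 1 and 2. At ZT5 it was 6, 1, 6 and 88 without PBS replicates 1 to 4 and 25, 5, 5 and 1 without vancomycin replicates 1 to 4. At ZT11 it ranged from 0 to 109, with 4 and 26 without PBS replicates 1 and 4 and 1, 10 and 109 without vancomycin replicates 1, 2 and 3. At ZT17 it ranged from 21 to 47, with 31 without PBS replicate 2 and 21 and 24 without vancomycin replicates 1 and 2, and at ZT23 from 0 to 1. The SPF interaction gave 41 to 83, time of day 671 to 1942 after PBS and 798 to 1717 after vancomycin. In GF mice the effect gave 0 to 0, the 4 times 0 to 0, 0 to 1, 0 to 0 and 0 to 1, the interaction 0 to 1, and time of day 15 to 66 after PBS and 14 to 69 after vancomycin. The difference gave 0 to 1, the lists 12 to 18 in SPF, 9 to 16 in GF and 17 to 22 for the difference, and the correlation of SPF and GF effects -0.215 to -0.0293.

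Replicate numbers recur in each group, but did not pair the samples: 6 of 16 same-numbered SPF pairs and 5 of 16 GF pairs had a correlation of deviations over 0.1, and 9 and 8 of 32 libraries correlated best with their own number. With the replicate number as a block the SPF effect held 157 genes, the SPF interaction 55 and the SPF lists 15.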

Other observations

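The histone group described here was chosen after the SPF calls were seen, and the lists tested at each time were added after the data were seen.

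Several histone genes were among those that fell in SPF mice given vancomycin. Of 44 histone genes tested, 7 fell and none rose in edgeR: the linker histones H1f2 (-0.53), H1f3 (-0.94), H1f0 (-0.42) and H1f4 (-0.93), and the core histones H4c4 (-0.89), H4c18 (-0.85) and H2bc6 (-0.60). The median of the 44 was -0.35 and 37 of them were negative, whether called or not. Because these calls prompted the choice of the group, no test of it on the same libraries is given. In GF mice 17 of 43 were negative (median 0.06). Most histone transcripts lack a poly(A) tail, and these libraries were poly(A)-selected, so values of both linker and core histones are uncertain.

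Gene lists were tested at each time, by fry against no change and by camera against other genes, and no difference between times was tested for a list. At SPF ZT11 the MHC class I list had a median of 0.58 (fry adjusted p = 0.0189; adjusted p = 0.0919 with an estimated correlation) and the pattern recognition list 0.28 (fry adjusted p = 0.0197; adjusted p = 0.0919 with an estimated correlation). Interferon-stimulated genes had SPF medians of 0.08, 1.11, 0.49 and 0.76 at ZT5, 11, 17 and 23 (fry adjusted p = 0.817, 0.0747, 0.673 and 0.925). Smooth muscle (median -0.58) and interstitial cell, neuron and glia genes (-0.56) lay lower at SPF ZT5 in camera (adjusted p = 1.38e-10 and 1.27e-04). T and NK cell (1.496) and B cell genes (1.35) lay higher there (camera adjusted p = 5.74e-07 and 1.06e-06). Fry gave an adjusted p = 0.297 for each but the B cell list (0.31), and an estimated correlation gave 0.604 for all. In GF mice at ZT23 the B cell (median -4.06), MHC class II (-2.82) and T and NK cell lists (-2.76) were lower in camera (adjusted p = 1.73e-15, 7.96e-09 and 2.59e-11), but each had an adjusted p = 0.118 by fry and 0.327 with an estimated correlation. In the same comparison adipose (2.33) and smooth muscle genes (0.84) lay higher and ribosomal protein genes (-0.38) lower in camera (adjusted p = 2.59e-11, 2.49e-07 and 2.4e-10), but at adjusted p = 0.118, 0.268 and 0.267 by fry and 0.327, 0.47 and 0.487 with an estimated correlation. Y-linked genes had a median of -1.52 (adjusted p = 0.0548). The colon position score of the 4 vancomycin libraries was -2.67, -5.45, 5.16 and 2.15, against 4.52 to 5.47 in the PBS libraries, and 3 of the 4 lacked Y-linked expression, against 1 of the 4 PBS libraries.

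Called genes lay near one another along chromosomes more than random sets in some other sets too. Among the SPF genes of the effect over all times, 36 of 136 placed genes lay within 10 tested genes of another (random median 20, 95th percentile 30, permutation p = 0.0056), and at ZT17 13 of 53 did (random 95th percentile 8, permutation p = 8e-04). Of the SPF genes that varied with time 1284 of 1502 did after PBS (random 95th percentile 1286, permutation p = 0.0775) and 1142 of 1384 after vancomycin (1152, permutation p = 0.189). Of the GF genes that varied with time, led by clock genes, 4 of 24 did after PBS and 3 of 24 after vancomycin (95th percentile 2 in each, permutation p = 0.0345 and 0.0381).

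Random splits of the libraries were used to ask whether chance can be excluded for each count. For the SPF effect over all times, 2 of 100 splits gave 137 genes or more (highest other 226), and for the time-of-day counts 1 of 100 did in SPF PBS (highest other 5), SPF vancomycin (highest other 6) and GF PBS (highest other 2) and 2 of 100 in GF vancomycin (highest other 1046). At SPF ZT17 1 of 35 did (highest other 1), the lowest share that 35 splits can give. Taken singly these shares lie under 5%, but they were not adjusted over the split tests. Such splits also cannot address cages or litters shared within a group. At SPF ZT5, 2 of 35 splits gave 14 genes or more (highest other 44), so chance is not excluded. Where the count was 0 every split gave as many: 35 of 35 at SPF ZT11 (highest other 789), SPF ZT23 (1), GF ZT5 (37), ZT11 (0), ZT17 (1) and ZT23 (3), 100 of 100 for the GF effect (highest other 1017) and the GF interaction (highest other 308), and 60 of 60 for the difference (highest other 24). Splits by treatment that reached 789 and 1017 genes against a real count of 0 point to a structure of the samples other than treatment, and a split by time that reached 1046 against 24 to one other than time of day. The first principal component, computed without the Hox genes of the position score, held 17.4% of the variance in SPF and 29.5% in GF libraries. Its Pearson correlation in size was 0.931 and 0.921 with the B cell score, 0.769 and 0.811 with smooth muscle, and 0.552 and 0.708 with colon position. Tissue makeup thus ran along the main axis of both, but whether it underlies those splits was not tested. For gene lists called by camera, 20 of 100 splits gave 15 or more in SPF mice (highest other 22), 69 of 100 gave 11 or more in GF mice (highest other 22), and 7 of 60 gave 18 or more for the difference (highest other 20). Chance is not excluded for these list counts.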
